A study of Acinetobacter baumannii with 8 samples.

How the data were processed

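RNA from 4 cultures of Acinetobacter baumannii was measured on 8 Agilent one-colour arrays. Per the labels' protocols, cultures grew in 10 ml of LB broth at 37 °C and 180 rpm for 12 h, were flash-frozen, and gave RNA by an RNeasy kit that was labelled with Cy3 by a Quick-Amp kit. The series' design text gives 1 sample without peptide and 3 with omega76, each with 2 technical replicates, and groups were taken from the labels. Per the file headers, the deposited scanner values are linear intensity values from Agilent Feature Extraction 11.5.1.1, background-subtracted and spatially detrended per spot but not normalized between arrays. The deposited value table of the whole series holds log2 values that the authors processed further; limma is named for this per the submitters' processing notes, without a version, and the scale factor and centring of that table are not stated. Set against each array's scanner signal across genes, its 8 columns had rank correlations of 0.995 to 0.999 and each matched its own array best, with higher values for brighter spots. Their medians were 7.46 to 7.48, and their low end was compressed. Their SDs were 1.89 to 1.93, against 2.45 to 3.05 for the log2 scanner signals. The 8 columns were thus nearly alike in distribution, as after quantile normalization, so the table and that alternative may not be independent. The table held 57 control features, and 0 columns of other samples were present.

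Each array had 15208 gene spots of 10621 probes for 3573 genes, plus 536 control spots. Control spots and 57 spots with outlier marks were left out, and spots of one probe were averaged. The main values were log2 processed signals minus the array's 75th percentile over gene spots. A probe was kept when it was well above background on both arrays of at least 1 culture, which left 9745 probes and 3314 genes; 259 genes were left out. A gene's value was the mean of its kept probes (3 probes for 3196 genes, 2 for 39 and 1 for 79). Of called genes with over 1 probe, 2.14%, 2.58% and 0.647% at the low, middle and high dose had a probe of the opposite sign. Precision was limited by the number of arrays, and the residual degrees of freedom were 4 between arrays and 2 between cultures, with a prior of 3.74 in the array-level fit.

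Genes are named as in the array design (identifiers beginning with ABAYE) with the product given there; 1168 carried a product named hypothetical. The gene table at hand, of 3901 genes from another assembly, matched 0 of the identifiers and was not used for names, and genomic coordinates are not given. For a gene not well above background on either array of the dimmer culture, the change is written as at least N-fold. The bound sets the brighter culture's mean against, per array of the dimmer culture, the higher of the lowest signal well above background and the gene's own signal.

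Tests used R 4.3.3 with limma 3.58.1 and statmod 1.5.0. Between cultures, lmFit and eBayes were run on all 8 arrays in 1 fit, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 with a change of at least 2-fold. The 5 comparisons were each dose against untreated and the adjacent doses against each other. The dose trend and the comparison of treated with untreated cultures were fitted to the 4 culture means, with no minimum change. Gene lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, which asks whether a list's genes move on balance one way and does not compare it with other genes. Of 32 lists, 31 could be tested; p-values were adjusted over lists within each comparison. Percentiles of list medians came from 10000 random lists matched on mean level.

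The sample groups, tests, alternatives, list names with their symbols and first product patterns, and the rule for named genes were fixed before the data were examined. Because the array names few gene symbols, further product-name patterns were added after the annotation was seen and before any fold change was computed; list tests with the first patterns alone are among the alternatives. Some members do not match their list's name: GreA, a transcription factor, sits among the translation factors, dehydroquinate enzymes sit in aromatic compound breakdown, and a serine/threonine dehydratase and a muramoyl ligase sit in amino acid synthesis. Succinate dehydrogenase, GreA, an HtrA-like protease and homogentisate dioxygenase belong to more than 1 list. Named genes were the 10 largest rises and 10 largest falls among called genes of known function at 0.5x MBC, the 5 and 5 at each lower dose, the 3 and 3 strongest trend statistics since none passed, and up to 4 called or 2 uncalled members of each list by size at 0.5x MBC.

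Alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, no filter on dim probes, probes well above background on all arrays, the brightest probe of a gene, the authors' value table, arrays or cultures left out in turn, a replicate block, the culture as a random block, the slide row, only the arrays compared, robust moderation, no minimum change, and dose as a rank. Cyclic loess, scaling to the spike-in probes and lists limited to the first patterns were chosen after seeing the data. The arrays were on 1 slide of 2 rows and read in 2 scans. The untreated and 0.1x MBC arrays shared a row, as did the 0.25x and 0.5x MBC arrays; the 6 treated arrays shared a scan.

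The fits were tested on simulated data with the real levels and spreads of the 3314 genes. For 0.5x MBC against untreated, 0, 22, 49 and 50 of 50 genes changed by 1.5-, 2-, 4- and 8-fold were recovered, with 0 false calls. For the dose trend with the residual spread of the real culture means around the dose line, 0 of 50 were recovered at each size. With array spread alone 27, 45, 48 and 50 were, with 7 false calls. A ribosomal protein list raised 1.5-fold was recovered among 31 lists with 0 others called. For that list and for 0.5x MBC against untreated, genes were simulated independently of each other and with array spread alone. The 0 others called and 0 false calls therefore give no rate of false calls for correlated genes or separate cultures.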

Results

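Transcript levels were measured in the Gram-negative bacterium Acinetobacter baumannii after growth with omega76, a designed antimicrobial peptide. Its minimum bactericidal concentration (MBC, the lowest concentration that kills the culture) was 4 µg/ml, and the series was made to describe the response of the transcriptome to exposure. There were 4 cultures: 1 untreated, and 1 each at 0.1x MBC, 0.25x MBC and 0.5x MBC, the low, middle and high dose. The RNA of each culture was hybridised to 2 one-colour Agilent arrays, so that 8 arrays carried probes for 3573 genes, of which 3314 could be tested. The 2 arrays of a culture were technical replicates. Adjusted p-values between arrays therefore measured the technical spread and compared these 4 cultures, not the doses in general, and the number of arrays limited the precision. The dose trend and the comparison of treated with untreated cultures counted each culture once.

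The 2 arrays of a culture resembled each other closely, with correlations across genes of 0.994 to 0.998. Between cultures, the untreated one correlated with 0.5x MBC at 0.913 across genes, and with 0.1x and 0.25x MBC at 0.731 and 0.750. Between 84.2% and 92.4% of gene spots were well above background on each array, and no spot was saturated. The spread of gene signals differed between cultures. The log2 interquartile range was 2.03 and 2.04 on the untreated arrays and 2.59 and 2.71 at 0.5x MBC, against 4.12 to 4.21 on the 0.1x and 0.25x MBC arrays. The log2 range of the spike-in control probes, 12.25 to 12.56, was nearly equal on all 8 arrays. All arrays lay on 1 slide, read in 2 scans; the untreated arrays alone made up 1 scan, so that scan and treatment coincided in every comparison with the untreated culture.

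**Figure D1:**
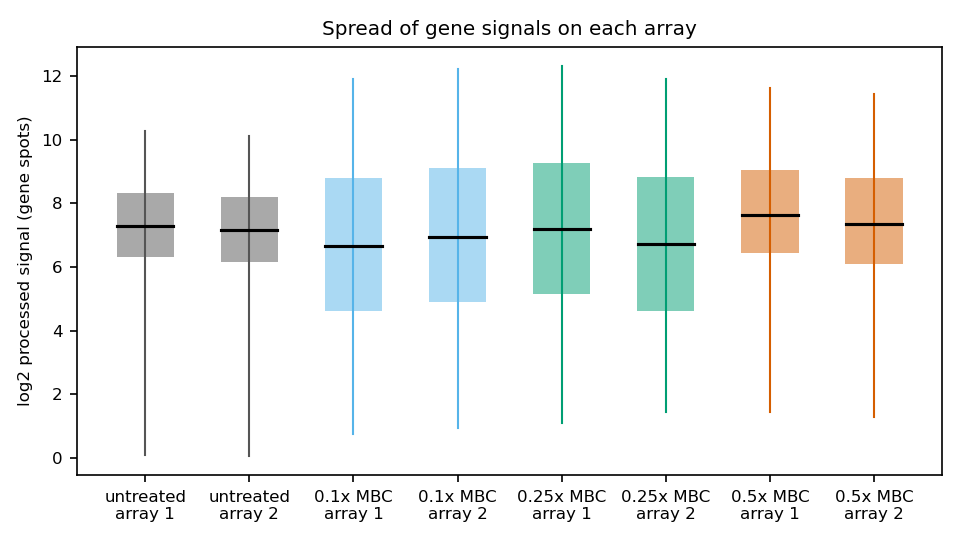
Spread of gene signals on each array. The vertical axis is the log2 processed signal of gene spots, boxes span the 25th to 75th percentile, black bars mark the median and lines the 5th to 95th percentile; boxes are narrowest on the untreated arrays (2.03 and 2.04) and widest at 0.1x and 0.25x MBC (4.12 to 4.21).

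Signals were scaled to each array's 75th percentile. On that scale the median log2 fold change of all genes against the untreated culture was -0.88 at 0.1x, -0.78 at 0.25x and -0.33 at 0.5x MBC. It was 0.23, 0.26 and 0.05 after median centring, and -1.62, -1.55 and -0.996 after scaling to the spike-in probes. Medians of gene lists against the untreated culture are therefore given also relative to the median of all genes. Values of single genes are log2 fold changes ± SE from 2 arrays per culture, with limma's adjusted p where printed.

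At 0.5x MBC, genes of aerobic energy production and of protein synthesis were higher than in the untreated culture. In the respiratory chain list, 22 of 29 measured members rose, 0 fell and 7 did not pass, with a median of 1.53, or 1.86 relative to all genes. Both subunits of the cytochrome d terminal oxidase, an oxygen reductase of high affinity, rose (ABAYE1637 by 2.65 ± 0.09 and ABAYE1636 by 2.10 ± 0.09), as did subunits A and B of NADH dehydrogenase, the proton-pumping entry point for electrons (ABAYE3060, 2.23 ± 0.11; ABAYE3059, 2.19 ± 0.08). The list of the TCA cycle, glyoxylate shunt and pyruvate dehydrogenase had 13 of 33 members risen and 0 fallen, with a median of 0.81, or 1.15 relative to all genes. Its highest members were methylcitrate synthase (ABAYE3792, 3.13 ± 0.09), an enzyme of propionate breakdown, aconitate hydratase (ABAYE3791, 3.00 ± 0.19) and the beta subunit of succinyl-CoA synthetase (ABAYE0783, 2.34 ± 0.12). Of 9 ATP synthase genes, 6 rose and 0 fell (median 1.24, or 1.57 relative to all genes), led by the gamma subunit (ABAYE3717, 2.31 ± 0.13) and the alpha subunit (ABAYE3718, 1.99 ± 0.25). The adjusted p with limma's camera was 1.24e-15 for the respiratory chain, 5.77e-09 for the TCA list and 2.21e-05 for ATP synthase. None of the 3 passed with an estimated correlation (adjusted p = 0.170, 0.175 and 0.170). Cyclic loess ended the calls of the TCA and ATP synthase lists (adjusted p = 0.0678 for each).

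Of 56 genes for ribosomal proteins, 30 rose at 0.5x MBC, 0 fell and 26 did not pass, with a median of 1.18, or 1.51 relative to all genes. Examples were S3 (ABAYE0414, 1.89 ± 0.09), S17 (ABAYE0417, 1.77 ± 0.14) and L2 (ABAYE0411, 1.76 ± 0.12). The adjusted p for the ribosomal proteins was 1.24e-15 and was 0.175 with an estimated correlation; cyclic loess ended the call (adjusted p = 0.770). Their median stood at percentile 94.3 of 10000 random lists matched on mean level, and genes of high level lay higher on the treated arrays in general. Among translation factors and tRNA synthetases, 5 of 37 rose and 0 fell (median 0.50; adjusted p = 0.000154, and 0.401 with an estimated correlation); spike-in scaling, which shifts all genes alike, put the median at -0.16, with 0.83 relative to all genes and the call kept. The ribosome recycling factor, which frees ribosomes after termination, was the highest (ABAYE1578, 2.02 ± 0.09). Elongation factor Tu, which brings aminoacyl-tRNA to the ribosome, rose at both of its loci (ABAYE2946, 1.74 ± 0.18; ABAYE3496, 1.39 ± 0.16). Each locus was read by 1 probe, copies this alike may share signal, and ABAYE3496 fell to -0.05 under cyclic loess.

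Among genes of known function, several of the largest rises at 0.5x MBC were in genes annotated to the breakdown of aromatic compounds or the transport of aromatic amino acids. Catechol 1,2-dioxygenase, which opens the ring of catechol, rose by 4.10 ± 0.08, or 17.1-fold (ABAYE1718; adjusted p = 1.27e-07). Beta-ketoadipyl-CoA thiolase (ABAYE1715, 1 probe) rose by 3.76 ± 0.20 and muconolactone isomerase (ABAYE1719) by 2.69 ± 0.08; both act later in the same route. An aromatic amino acid transporter (ABAYE1031) rose by 3.18 ± 0.16, an indolepyruvate decarboxylase (ABAYE1030) by 3.03 ± 0.10, and the subunits of an aromatic-ring-hydroxylating dioxygenase by 3.15 ± 0.09 (ABAYE1704) and 2.92 ± 0.14 (ABAYE1705). A reductase component annotated to p-hydroxyphenylacetate hydroxylase rose by 3.07 ± 0.10 (ABAYE1708). The list of aromatic compound breakdown as a whole went both ways, with 11 of 52 members risen and 13 fallen (median -0.34, or -0.01 relative to all genes; adjusted p = 0.339), and its median lay above 0 with median centring (0.04) and cyclic loess (0.06). Outside these routes, coproporphyrinogen III oxidase, an enzyme of heme synthesis, rose by 3.21 ± 0.15 (ABAYE0378).

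Genes for trehalose synthesis were among those that fell most at 0.5x MBC. Trehalose is a protective sugar of many bacteria; trehalose-6-phosphate synthase (ABAYE3007) changed by -2.07 ± 0.12 and the phosphatase of the same route (ABAYE3006) by -1.59 ± 0.09. A short-chain dehydrogenase (ABAYE2269) changed by -2.13 ± 0.09, a protein annotated as competence-damaged (ABAYE2272) by -1.90 ± 0.20, and an aminotransferase (ABAYE0111) by -1.83 ± 0.09. An antioxidant protein (ABAYE0619) stood at -1.70 ± 0.10 and a ferredoxin-NADP+ reductase (ABAYE1186) at -1.66 ± 0.11. Fallen regulators were 2 of the LysR family (ABAYE2827, -1.70 ± 0.14; ABAYE2327, -1.66 ± 0.12), and an arylsulfatase (ABAYE2815) stood at -1.60 ± 0.14. Cyclic loess ended the calls of ABAYE2327 and ABAYE2815, and the authors' value table that of ABAYE2815. None of the other 18 genes with the largest rises and falls lost its call under any alternative.

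**Figure D2:**
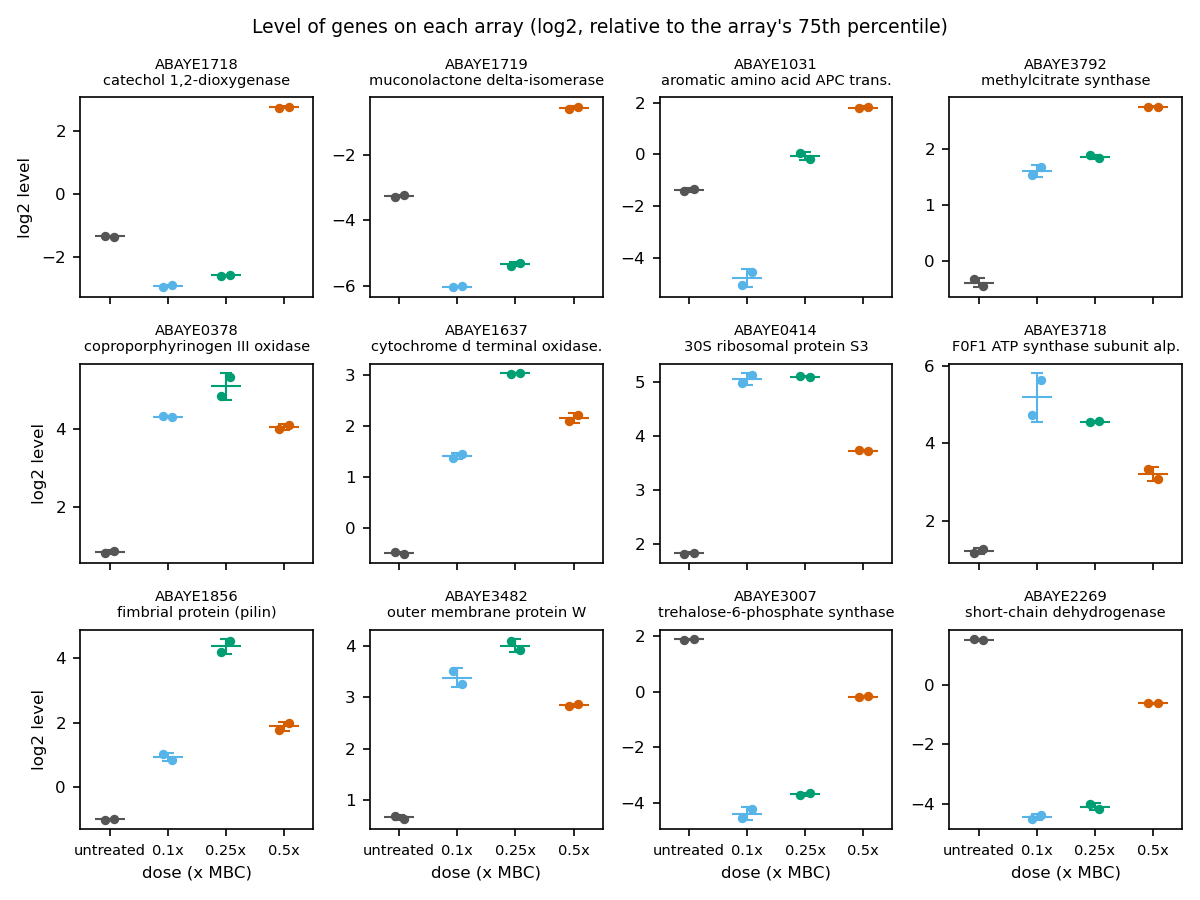
Level of selected genes on each array, as log2 signal relative to the array's 75th percentile, against the dose in x MBC. Points are the 2 arrays of a culture, bars the mean ± SD; catechol 1,2-dioxygenase (ABAYE1718) rose by 4.10 at 0.5x MBC, and trehalose-6-phosphate synthase (ABAYE3007) stood at -6.28, -5.58 and -2.07 against untreated at the low, middle and high dose.

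In lists of the cell envelope, where cationic peptides first bind, calls at 0.5x MBC went both ways. In lipid A and LOS core synthesis, 0 of 15 members passed; the phosphoethanolamine transferase annotated with polymyxin resistance (ABAYE0731) stood at -0.71 ± 0.10. In LOS, lipoprotein and phospholipid transport to the outer membrane, 2 of 16 rose and 0 fell, among them the peptidoglycan-associated lipoprotein (ABAYE0901, 1.27 ± 0.08). Of 29 outer membrane proteins and their assembly factors, 3 rose and 5 fell, with OmpW, a beta-barrel protein of the outer membrane, highest (ABAYE3482, 2.20 ± 0.11) and a dicarboxylate porin lowest (ABAYE2299, -1.28 ± 0.10). Peptidoglycan synthesis and remodelling had 2 risen and 2 fallen of 30, and envelope stress and two-component regulators 4 risen and 5 fallen of 31. In capsule and exopolysaccharide, 3 of 20 rose and 1 fell; UTP-glucose-1-phosphate uridylyltransferase (ABAYE3803) rose by 1.70 ± 0.10. None of these 6 lists passed, with adjusted p from 0.165 to 0.613. Drug efflux had 0 risen and 6 fallen of 33 (median -0.61, or -0.28 relative to all genes; adjusted p = 0.339), with a multidrug ABC transporter lowest (ABAYE1174, -1.38 ± 0.12). Of 8 antibiotic resistance enzymes, 4 rose and 0 fell (adjusted p = 0.173). They included an aminoglycoside nucleotidyltransferase (ABAYE3622, 1.97 ± 0.11) and beta-lactamase OXA-10 (ABAYE3619). OXA-10 was not well above background in the untreated culture and was at least 1.13-fold higher at 0.5x MBC. With normexp OXA-10 stood at -0.28 and was not called. All 4 calls ended with the authors' value table, and of the 4 only OXA-10 kept its call with quantile normalization.

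Of the stress lists, heat shock, chaperones and proteases passed at 0.5x MBC, with 5 of 29 risen and 0 fallen (median 0.37; adjusted p = 0.00130, and 0.170 with an estimated correlation). Its highest members were the membrane protease HtpX (ABAYE0829, 1.46 ± 0.09) and the chaperone HchA (ABAYE0719, 1.31 ± 0.08). With spike-in scaling the median was -0.29 and, relative to all genes, still 0.70 for heat shock, chaperones and proteases; the call ended with quantile normalization, cyclic loess, the authors' value table and the first product patterns alone (adjusted p = 0.0518). Oxidative stress defence had 3 risen and 3 fallen of 23, and DNA repair and SOS response 0 risen and 4 fallen of 32, with a UmuC-like protein lowest (ABAYE1540, -1.42 ± 0.13). Iron uptake and storage had 3 risen and 8 fallen of 36; both bacterioferritins, which store iron, rose (ABAYE0307, 1.74 ± 0.11; ABAYE3009, 1.71 ± 0.09), and TonB, which powers siderophore uptake, fell (ABAYE2047, -1.33 ± 0.09). Osmoprotection and potassium uptake had 0 risen and 3 fallen of 17, and toxin-antitoxin and stationary-phase or desiccation proteins 2 risen and 0 fallen of 12. These last 5 lists did not pass (adjusted p from 0.173 to 0.525).

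In biosynthesis, purine and pyrimidine synthesis passed at 0.5x MBC with 4 of 28 risen and 0 fallen (median 0.17; adjusted p = 0.00184, and 0.175 with an estimated correlation), among them the beta subunit of ribonucleotide reductase (ABAYE3067, 1.42 ± 0.10). Fatty acid and phospholipid synthesis passed with 1 risen and 1 fallen of 23 (median 0.33; adjusted p = 0.0134, and 0.175 with an estimated correlation), RNA polymerase and sigma factors with 3 risen and 0 fallen of 13 (median 0.34; adjusted p = 0.0394, and 0.201 with an estimated correlation), and cell division with 0 called of 14 (median 0.21; adjusted p = 0.0337, and 0.201 with an estimated correlation). Under spike-in scaling, which shifts all genes alike, the 4 medians were -0.49, -0.34, -0.33 and -0.46 but stayed at 0.50, 0.66, 0.67 and 0.54 relative to all genes, and none of the 4 passed (adjusted p = 0.0742, 0.111, 0.0742 and 0.212). None passed with cyclic loess either, and only purine and pyrimidine synthesis passed with quantile normalization and with the authors' value table. Cell division also did not pass without the filter on dim probes (adjusted p = 0.0564), without replicate 2 at 0.5x MBC (0.0540) or with the first patterns (0.213). RNA polymerase and sigma factors did not with median centring (0.0648), without that replicate (0.0540), with either other probe filter (0.0626 and 0.0600) or with the brightest probe (0.206). The median of RNA polymerase and sigma factors was negative also under quantile normalization (-0.21), cyclic loess (-0.43) and the authors' value table (-0.27), as was that of fatty acid and phospholipid synthesis under cyclic loess (-0.08). Amino acid synthesis had 1 risen and 7 fallen of 92 and did not pass (adjusted p = 0.525). Fatty acid and phenylacetate breakdown had 6 risen and 2 fallen of 53 (adjusted p = 0.360), with the alpha subunit of the fatty acid oxidation complex highest (ABAYE3470, 1.88 ± 0.20), and histidine and other amino acid breakdown 6 risen and 6 fallen of 31 (adjusted p = 0.525). In pili, adhesins and biofilm, 5 of 45 rose and 3 fell (adjusted p = 0.598), and in protein secretion (Sec, Tat, T2SS, T6SS) 5 of 28 rose and 1 fell (adjusted p = 0.173). Phage, transposon and integron genes had 7 risen and 10 fallen of 37 (adjusted p = 0.851); a transposase (ABAYE3650) was at least 2.12-fold higher, though it stood at -0.10 with normexp. Acetoin and pyruvate oxidation had 0 called of 5 (adjusted p = 0.924). Quorum sensing and surface motility had 3 members on the array, too few for a list test, and its signal synthase (ABAYE3761) stood at -0.85 ± 0.23, without a call.

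**Figure D3:**
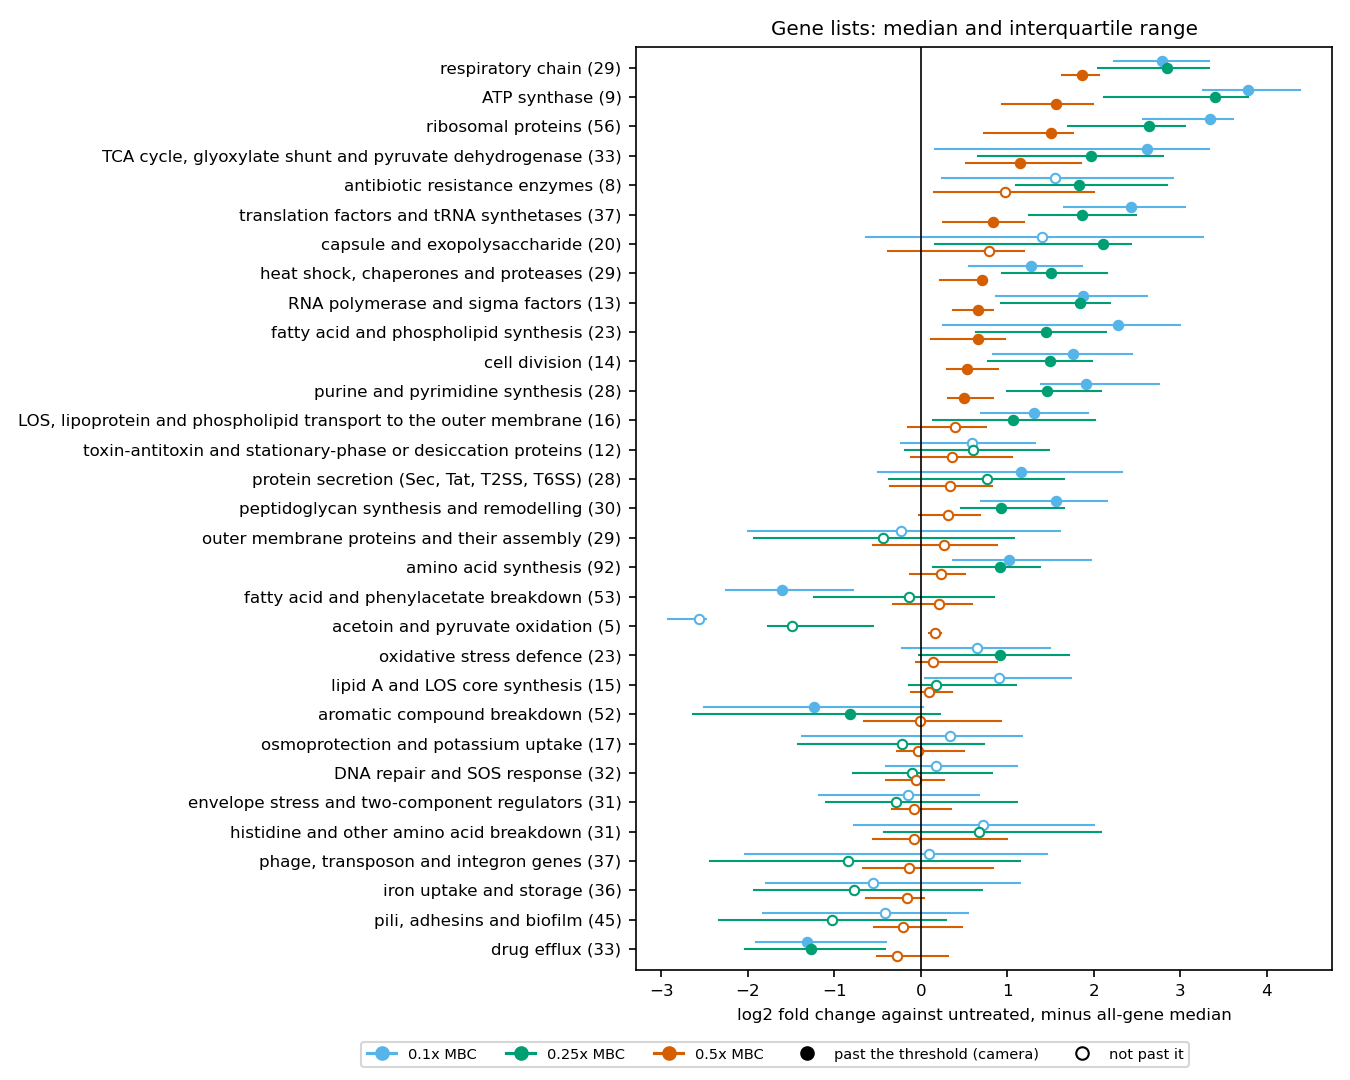
Median (points) and interquartile range (lines) of the members' log2 fold change against the untreated culture, minus the median of all genes, for the 31 tested lists at the low, middle and high dose; numbers in brackets are measured members. Filled points passed limma's camera with a preset correlation; respiratory chain, ATP synthase and ribosomal proteins lay highest at 0.5x MBC (1.86, 1.57 and 1.51), and RNA polymerase and sigma factors turned negative there under quantile normalization (-0.14).

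In total 648 genes were called at 0.5x MBC, 270 higher and 378 lower, at an adjusted p under 0.05 and a change of at least 2-fold. The share of higher calls, 41.7%, rested on the scaling: it was 54.7% with quantile normalization (352 higher, 292 lower), 89.7% with median centring (486 and 56), 74.2% with normexp (216 and 75), 55.6% with the authors' value table (245 and 196), 67.5% with cyclic loess (181 and 87) and 4.96% with spike-in scaling (86 and 1647). Of the 31 lists tested, 10 passed, all upwards; 0 passed with an estimated correlation, and 1, the respiratory chain, passed with cyclic loess. The medians of 3 of the 10 lay outside the central 95% of lists matched on mean level: the respiratory chain, the TCA list, and translation factors and tRNA synthetases (percentiles 100, 98.1 and 99.2). The others did not, among them ATP synthase (93.7), heat shock, chaperones and proteases (87.5), purine and pyrimidine synthesis (59.5) and RNA polymerase and sigma factors (28.5). Among the list examples, cyclic loess ended the calls of ABAYE3717, ABAYE3718, ABAYE0414, ABAYE0417, ABAYE0411, ABAYE2946, ABAYE3496, ABAYE0901, ABAYE2299, ABAYE1174, ABAYE3622, ABAYE0829, ABAYE1540, ABAYE2047 and ABAYE3067, and spike-in scaling those of ABAYE3496, ABAYE0901, ABAYE0829, ABAYE0719 and ABAYE3067. The authors' value table ended those of ABAYE0411, ABAYE2946, ABAYE3496, ABAYE1174, ABAYE3622, ABAYE2047, ABAYE3619 and ABAYE3650, quantile normalization those of ABAYE0411, ABAYE2946, ABAYE3496, ABAYE1174, ABAYE3622 and ABAYE2047, median centring those of ABAYE2299, ABAYE1174 and ABAYE2047, and normexp those of ABAYE1174, ABAYE2047, ABAYE3619 and ABAYE3650. ABAYE1174 was also not called from its brightest probe alone or from probes above background on all arrays. In every list and comparison, the number of members called when adjusted over the list alone equalled that over all genes. For several lists that did not pass, such as amino acid synthesis, outer membrane proteins and their assembly, and oxidative stress defence, the median was below 0 while the test, which compares with all other genes, leaned upwards.

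At 0.1x MBC the untreated and treated cultures differed more widely, with the same machinery of growth high and the breakdown of fatty acids and aromatic compounds low. Of the ribosomal proteins, 51 of 56 rose and 1 fell (median 2.46, or 3.34 relative to all genes), all 9 ATP synthase genes rose (median 2.90, or 3.78 relative to all genes), and 25 of 29 respiratory chain genes rose with 0 fallen (median 1.91, or 2.79 relative to all genes). Single genes with the largest rises were phosphoribosylglycinamide formyltransferase of purine synthesis (ABAYE0888, 4.01 ± 0.11), the alpha subunit of ATP synthase (ABAYE3718, 3.96 ± 0.25), a reductoisomerase of isoprenoid synthesis (ABAYE1581, 3.92 ± 0.09) and histidine ammonia-lyase, the entry enzyme of histidine use (ABAYE0076, 3.82 ± 0.12). Beta-lactamase OXA-10 (ABAYE3619) was at least 4.04-fold higher, a call that ended with normexp and with the authors' value table. The largest falls were in trehalose synthesis (ABAYE3006, -7.90 ± 0.09; ABAYE3007, -6.28 ± 0.12), a carnitine dehydratase-like transferase (ABAYE2345, -6.25 ± 0.16), the short-chain dehydrogenase (ABAYE2269, -5.96 ± 0.09) and ABAYE2272 (-5.68 ± 0.20).

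The lists of fatty acid and phenylacetate breakdown, aromatic compound breakdown and drug efflux moved down at 0.1x MBC. In fatty acid and phenylacetate breakdown, 45 of 53 fell and 0 rose (median -2.49, or -1.61 relative to all genes; adjusted p = 4.16e-05, and 0.24 with an estimated correlation). In aromatic compound breakdown, 37 of 52 fell and 0 rose (median -2.11, or -1.23 relative to all genes; adjusted p = 0.000172, and 0.271 with an estimated correlation), including catechol 1,2-dioxygenase (ABAYE1718, -1.59 ± 0.08) and muconolactone isomerase (ABAYE1719, -2.79 ± 0.08). Drug efflux had 26 fallen and 3 risen of 33 (median -2.19, or -1.31 relative to all genes; adjusted p = 0.0201, and 0.172 with an estimated correlation). All 5 genes of acetoin and pyruvate oxidation fell, while the list itself did not pass (adjusted p = 0.0550). The polymyxin-associated phosphoethanolamine transferase (ABAYE0731) changed by -2.66 ± 0.10 and the quorum-sensing signal synthase (ABAYE3761) by -3.41 ± 0.23. The 14 lists that passed upwards included ribosomal proteins (adjusted p = 3.45e-21, and 0.0828 with an estimated correlation), translation factors and tRNA synthetases (27 of 37 risen, 3 fallen; adjusted p = 2.5e-11, and 0.109 with an estimated correlation), and purine and pyrimidine synthesis (14 of 28 risen, 0 fallen; adjusted p = 3.14e-08, and 0.0828 with an estimated correlation). Of these, RNA polymerase and sigma factors turned to -0.07 with cyclic loess, and protein secretion (Sec, Tat, T2SS, T6SS) to -0.15.

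The comparison called 2114 genes, 547 higher and 1567 lower, so that 25.9% were higher; this share was 50.9% with quantile normalization (859 higher, 827 lower), 55.5% with median centring (1137 and 913), 51.0% with the authors' value table (612 and 587), 47.0% with cyclic loess (637 and 717) and 11.3% with spike-in scaling (262 and 2064). With normexp the share was 27.8% (468 and 1214), near the main one. The total was 1199 with the authors' table and 1354 with cyclic loess. In all, 17 lists passed and 0 did with an estimated correlation. The medians of 12 of the 17 lay outside the central 95% of lists matched on mean level.

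At 0.25x MBC the largest rises of single named genes included 3 fimbrial genes. The pilin (ABAYE1856) rose by 5.38 ± 0.13, or 41.5-fold, its chaperone (ABAYE1857) by 5.08 ± 0.17 and the fimbrial adhesin (ABAYE1859) by 4.49 ± 0.14. At 0.1x MBC the 3 genes stood at 1.94, 1.72 and 1.33, and at 0.5x MBC at 2.89, 2.87 and 2.23. The list of pili, adhesins and biofilm otherwise leaned down, with 5 risen and 28 fallen of 45, and did not pass (adjusted p = 0.0973). Coproporphyrinogen III oxidase (ABAYE0378) rose by 4.26 ± 0.15 and the cytochrome d oxidase subunit (ABAYE1637) by 3.53 ± 0.09. Beta-lactamase OXA-10 (ABAYE3619) was at least 3.71-fold higher, which normexp and the authors' value table did not call. Trehalose phosphatase (ABAYE3006, -6.81 ± 0.09), ABAYE2345 (-6.01 ± 0.16), ABAYE2269 (-5.61 ± 0.09) and trehalose synthase (ABAYE3007, -5.58 ± 0.12) fell most, and ABAYE2272, not well above background there, was at least 29.5-fold lower.

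Respiratory chain genes rose in 26 of 29 cases at 0.25x MBC (median 2.07, or 2.85 relative to all genes; adjusted p = 1.06e-13, and 0.0898 with an estimated correlation), and ribosomal proteins in 41 of 56 with 2 fallen (median 1.86, or 2.63 relative to all genes; adjusted p = 9.17e-17, and 0.115 with an estimated correlation). Capsule and exopolysaccharide had 11 risen and 3 fallen of 20 (median 1.33, or 2.11 relative to all genes; adjusted p = 0.00521, and 0.222 with an estimated correlation). Heat shock, chaperones and proteases had 12 risen and 2 fallen of 29 (median 0.72; adjusted p = 1.92e-05, and 0.0898 with an estimated correlation), with a median of -0.05 under spike-in scaling, or 1.501 relative to all genes. Aromatic compound breakdown had 33 fallen and 1 risen of 52 (median -1.60, or -0.82 relative to all genes; adjusted p = 0.00615, and 0.397 with an estimated correlation), and drug efflux 25 fallen and 3 risen of 33 (median -2.05, or -1.27 relative to all genes; adjusted p = 0.0124, and 0.165 with an estimated correlation). Altogether 18 lists passed, 16 upwards and 2 downwards, and 0 with an estimated correlation. Only 8 of the 18 had medians outside the central 95% of lists matched on mean level. The count of genes was 1986, with 493 higher and 1493 lower (24.8% higher). The share was 49.9% with quantile normalization (812 and 815), 56% with median centring (1141 and 898), 49.9% with the authors' value table (561 and 564), 49.5% with cyclic loess (608 and 621) and 8.97% with spike-in scaling (201 and 2040). With normexp the share was 31.5% (406 and 884). The total was 1290 with normexp, 1125 with the authors' table and 1229 with cyclic loess.

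The adjacent doses 0.1x and 0.25x MBC were read in the same scan but lay on different rows of the slide. Between them, genes of fatty acid use and of acetoin oxidation were higher and ribosomal protein genes lower at the higher dose. In fatty acid and phenylacetate breakdown, 29 of 53 were higher at 0.25x MBC and 0 lower (median 1.14; adjusted p = 5.16e-10, and 0.272 with an estimated correlation). Ribosomal proteins had 10 of 56 lower and 0 higher (median -0.56; adjusted p = 1.33e-06, and 0.361 with an estimated correlation). Acetoin and pyruvate oxidation had 3 of 5 higher (median 1.32; adjusted p = 0.00350, and 0.272 with an estimated correlation), and oxidative stress defence 4 of 23 higher and 0 lower (median 0.43; adjusted p = 0.0199, and 0.361 with an estimated correlation). In all 490 genes were called, 302 higher and 188 lower, and 10 lists, 3 upwards and 7 downwards. Of the 10 lists, 9 had medians outside the central 95% of lists matched on mean level. The count of genes was 255 with normexp and 213 with the authors' values.

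Between 0.25x and 0.5x MBC, which shared a scan and a row of the slide, breakdown, export and mobile-element genes were higher at the higher dose. Aromatic compound breakdown had 33 of 52 higher and 1 lower (median 1.73, or 1.24 relative to all genes; adjusted p = 0.000111, and 0.238 with an estimated correlation), and drug efflux 23 of 33 higher and 0 lower (median 1.55, or 1.06 relative to all genes; adjusted p = 0.00397, and 0.126 with an estimated correlation). Of phage, transposon and integron genes, 22 of 37 were higher and 0 lower (median 1.93, or 1.43 relative to all genes; adjusted p = 0.0281, and 0.126 with an estimated correlation). The other 16 lists that passed leaned down, among them ribosomal proteins with 5 of 56 lower and 1 higher (median -0.71, or -1.20 relative to all genes; adjusted p = 1.22e-13, and 0.126 with an estimated correlation). Of the 19 lists that passed, 9 had medians outside the central 95% of lists matched on mean level. The median of all genes was 0.49 in this comparison. The call count was 1383, with 1217 higher and 166 lower (88.0% higher), and the share higher was 58.3% with quantile normalization (487 and 348), 49.4% with median centring (739 and 756), 73.4% with normexp (314 and 114), 65.5% with the authors' value table (290 and 153) and 57.2% with cyclic loess (475 and 356).

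Across the 4 cultures, no gene had a linear dose slope that passed limma's test on culture means (lowest adjusted p 1.00, with 1 gene at an unadjusted p under 0.05). This test recovered 0 of 50 simulated genes even at 8-fold with the residual spread of the real culture means around the dose line. With 1 culture per dose, that spread holds differences between cultures and any response to dose that is not linear. These cannot be told apart here, and the lack of calls does not speak against changes with dose. The steepest statistics, given only as values, were a glycine tRNA (ABAYEtRNA36) at 5.68 per 1x MBC, methylcitrate synthase (ABAYE3792) at 5.35 and beta-ketoadipyl-CoA thiolase (ABAYE1715) at 8.42, and in the other direction the antioxidant protein (ABAYE0619) at -3.23, 3-dehydroquinate dehydratase (ABAYE1539) at -3.03 and an amino acid ABC transporter protein (ABAYE2257) at -3.11. Without the 0.5x MBC culture the slope of ABAYE1715 was -3.57. As lists, the respiratory chain (median slope 1.97, adjusted p = 4.01e-11), fatty acid and phenylacetate breakdown (1.51, adjusted p = 2.25e-07), the TCA cycle, glyoxylate shunt and pyruvate dehydrogenase (0.99, adjusted p = 2.17e-05) and aromatic compound breakdown (0.14, adjusted p = 0.000539) passed upwards. None of the 4 passed with an estimated correlation (adjusted p = 0.985 for each) or with fry. Without the untreated culture the slopes of the respiratory chain and TCA lists turned negative, and without the 0.5x MBC culture that of aromatic compound breakdown did (adjusted p = 4.15e-05, 0.00213 and 0.00552). Fatty acid and phenylacetate breakdown did not pass without the 0.5x MBC culture (adjusted p = 0.925) or without the 0.1x MBC culture (0.351), and aromatic compound breakdown did not without the latter (0.314) or with dose as a rank (0.231). With the slide row as a covariate the slopes of the respiratory chain, TCA, and fatty acid and phenylacetate breakdown lists turned negative (adjusted p = 0.469, 0.701 and 0.0467).

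With the 3 treated cultures set against the untreated one, 0 genes passed limma's test (lowest adjusted p 0.381); at an unadjusted p under 0.05 there were 174, of which 111 were higher and 63 lower. Without the 0.5x MBC culture the count was 1308, with 236 higher and 1072 lower, and without the 0.25x MBC culture 1. By camera 18 lists passed, 16 upwards and 2 downwards, led by ribosomal proteins (median 1.85, or 2.49 relative to all genes; adjusted p = 2.44e-24) and the respiratory chain (median 1.89, or 2.53 relative to all genes; adjusted p = 1.41e-20); drug efflux (median -1.58, or -0.94 relative to all genes; adjusted p = 0.0189) and aromatic compound breakdown (median -1.21, or -0.58 relative to all genes; adjusted p = 0.0321) were those downwards. The estimated correlation was not computed for this comparison.

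Calls in the same direction at all 3 doses were made for 519 genes, 178 higher and 341 lower, among them methylcitrate synthase (ABAYE3792), coproporphyrinogen III oxidase (ABAYE0378), S3 (ABAYE0414) and OmpW (ABAYE3482) on the higher side and the trehalose genes (ABAYE3006, ABAYE3007) on the lower. The pair 0.1x and 0.25x MBC shared 382 higher and 1330 lower genes, where independent lists would share 81.4 and 706. The pair 0.1x and 0.5x MBC shared 182 and 348 (independent lists 44.6 and 179), and the pair 0.25x and 0.5x MBC 214 and 354 (40.2 and 170). Unchanged arrays simulated with the technical array spread alone shared 0.01 to 0.03 genes on average over 100 draws. The simulation held no spread between cultures, so it gives no baseline for separate cultures. Any deviation of the 1 untreated culture enters all 3 comparisons. The covariance of log2 fold changes across genes was 2.90, 0.964 and 1.096 for the 3 pairs, against 0.0093 simulated with array spread alone. The correlations were 0.893, 0.662 and 0.784, against 0.50 in the same simulation. With 2 untreated arrays of 1 culture, the controls could not be split into parts of at least 2 arrays, so part of the excess may come from the shared controls.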

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

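Of the tests weighed in this part, those of the separate scan, for the spread of gene levels and for the ribosomal proteins, and of the slide row for each breakdown list alone were chosen after the results they bear on were seen. With 1 culture per dose, a difference in the peptide's effect and a difference between cultures stay open for every pattern, since neither was tested.

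Differences between doses drew attention to single genes called in opposite directions against the untreated culture, with the difference between the doses itself past limma's threshold. That last condition removed no gene and adds no support, since opposite calls of at least 2-fold already set the doses far apart. Such genes numbered 23 between 0.1x and 0.25x MBC (14 lower then higher, 9 the reverse), 37 between 0.1x and 0.5x MBC (31 and 6) and 17 between 0.25x and 0.5x MBC (13 and 4). Directions of calls near 2-fold rest on the scaling, and opposite calls were not counted under other scalings. The all-gene median against untreated was -0.88, -0.78 and -0.33 over the 3 doses, but 0.23, 0.26 and 0.05 with median centring. The aromatic amino acid transporter (ABAYE1031) stood at -3.41, 1.30 and 3.18 over the 3 doses, the ring-hydroxylating dioxygenase subunit (ABAYE1704) at -3.59, -0.86 and 3.15, catechol 1,2-dioxygenase (ABAYE1718) at -1.59, -1.24 and 4.10, and muconolactone isomerase (ABAYE1719) at -2.79, -2.10 and 2.69. In the other direction, an amino acid ABC transporter protein (ABAYE2256) stood at 2.87, 1.28 and -1.17; it was picked after its values were seen.

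Whole lists also differed between 0.5x and 0.1x MBC, which was not among the 5 comparisons set out above. Of 31 lists tested, 21 passed camera, 5 upwards and 16 downwards, and 0 passed with an estimated correlation. The lists given here are a selection of those, and their medians are not relative to all genes. The median difference was -1.32 for ribosomal proteins (adjusted p = 1.4e-18, and 0.0957 with an estimated correlation) and -0.64 for the respiratory chain (adjusted p = 8.73e-05, and 0.152 with an estimated correlation). It was 2.24 for fatty acid and phenylacetate breakdown (adjusted p = 1e-06, and 0.168 with an estimated correlation) and 1.85 for aromatic compound breakdown (adjusted p = 1.41e-05, and 0.205 with an estimated correlation). Relative to all genes, the difference of the respiratory chain lay near 0 with cyclic loess (0.01) and was negative under the other scalings.

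The first pattern weighed was the narrow spread of gene levels on the untreated and 0.5x MBC arrays. The prediction was that signal added to every probe alike would leave probes of 1 gene unrelated among the genes lowest at 0.1x MBC. The share of probe variance between those genes was 0.731 on the untreated arrays (bootstrap range 0.683 to 0.775) and 0.338 at 0.1x MBC. A constant signal shrinks log2 differences within and between genes together. Genes picked as low at 0.1x MBC may also be expressed in the untreated culture. The share need not fall, so this test cannot decide. Compression during labelling or hybridisation, or in the separate scan of the untreated arrays, would narrow the spike-in probes too, and their log2 range there was 0.988 times that at 0.1x MBC. That range rests on the outermost probes. Gene spots narrowed little from the 5th to 95th percentile (10.19 and 10.06 untreated, 11.16 and 11.29 at 0.1x MBC). The 5th percentile lay near the background floor, though. On the first array of each culture its signal was 1.05 untreated and 1.69 at 0.1x MBC, against negative-control medians of 1.02 and 1.59. Over tested genes the SD of levels was 1.54 untreated and 2.63 at 0.1x MBC. Of the 8 spike-in probes used, none departed by more than 0.258 (log2) from the common offset between these cultures. Signal added to every probe alike thus stays open. Added signal that is particular to each gene, such as carried-over DNA, may also play a part and was not tested. A flatter distribution of transcripts in these cultures is a further hypothesis.

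The second pattern was the higher level of ribosomal proteins in the 3 treated cultures. The list's median stood at percentiles 100, 97.9 and 94.3 of lists matched on mean level at the low, middle and high dose, so at 0.5x MBC a general rise of bright genes with the array spread and a rise of this list cannot be told apart. A separate scan of the untreated arrays could shift every signal, but no spike-in probe departed by more than 0.279 (log2) from the common offset, against shifts of the list relative to all genes of 3.34, 2.63 and 1.51. That test replaced a prediction that no value could exclude the scan, which had overlooked the spike-in probes. A difference in growth stage between the cultures after 12 h is a candidate explanation that no value here tested.

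The third pattern was the higher level of both breakdown lists, fatty acid and phenylacetate and aromatic, at 0.5x than at 0.1x MBC. The 105 genes had a median difference of 2.12, at percentile 100 of random lists matched on mean level (matched median 0.84), which argues against the differing array spread as the whole cause. Between 0.25x and 0.5x MBC, which share a slide row, the percentile was 99.8 for both lists together, a bound that was too loose since 1 list could carry it: it was 100 for aromatic compound breakdown and 96.6 for fatty acid and phenylacetate breakdown alone. This argues against the row as the whole cause for the aromatic list only; for the fatty acid list, whose dose slope turned with the row as a covariate (adjusted p = 0.0467), row and dose cannot be told apart. A hypothesis that remains is a changed use of carbon sources along the doses, which may equally reflect how far each single culture had grown.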

How the results depend on the processing

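Cyclic loess, spike-in scaling and lists with the first product patterns alone were chosen after the results were seen. Of 3331 recomputed values of 151 named gene results, 3054 stayed on their side of the threshold, 254 lost the call, 17 gained it and 6 turned with a call before or after; among uncalled values, ABAYE1944 at 0.5x MBC and the slope of ABAYE1715 also changed sign (to 0.28 with cyclic loess and -3.57 without the 0.5x MBC culture); of 321 recomputed list calls, 263 stayed, 48 were lost and 10 turned. Below background the level is a bound, and normexp, which treats it otherwise, turned OXA-10 (ABAYE3619) to -0.28, ABAYE3630 to -0.25, ABAYE3811 to -0.27, ABAYE3650 to -0.10 and ABAYE0574 to -0.26 at 0.5x MBC. Cyclic loess turned ABAYE3496 to -0.0542. Where a value moved, the cause was not tested.

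Gene counts moved as follows in the order low, middle and high dose against untreated, 0.25x against 0.1x and 0.5x against 0.25x MBC. Normexp gave 1290, 291, 255 and 428 from 0.25x MBC on (284 of the 291 shared with the main result). The authors' value table gave 1199, 1125, 213 and 443, leaving 0.5x MBC within range. Cyclic loess gave 1354, 1229 and 268 for the doses (171 of the 268 shared) and 831 for the last. Quantile normalization gave 835 for the last, spike-in scaling 1733 at 0.5x MBC (464 shared), and no minimum change 2481, 2001 and 2679 for the last 3. The overlap of calls over the 3 doses was 1972 with no minimum change and 519 with it.

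Leaving out an array gave 2106 to 2140, 1965 to 2008, 533 to 779, 483 to 550 and 1351 to 1426 genes, where a lone array was assumed to vary like the others. Leaving out an array or a culture gave 0 to 3 genes for the dose trend (3, all lower, without the 0.5x MBC culture) and 0 to 1308 for treated against untreated cultures (1308 without the 0.5x MBC culture). Lists at 0.5x MBC numbered 8 to 10 and trend lists 4 to 20.

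Among 31 lists tested at 0.5x MBC, 10 passed in the main setting, 6 with quantile normalization, 6 with the authors' table, 1 with cyclic loess, 4 of 21 with the first patterns, 24 with fry (14 higher, 10 lower) and 0 with an estimated correlation. RNA polymerase and sigma factors turned with quantile normalization, the authors' table and cyclic loess (adjusted p = 0.915, 0.980 and 0.646), and fatty acid and phospholipid synthesis with cyclic loess (0.770). Among 31 lists tested for trend, 4 passed in the main setting, 7 with no filter on dim probes, 7 with cyclic loess, 10 with spike-in scaling, 7 with ranked dose, 11 with the slide row as a covariate, and 0 with an estimated correlation or fry. Without the untreated culture 20 passed, without 0.1x MBC 8 and without 0.5x MBC 18. Respiratory chain and TCA slopes turned without the untreated culture (4.15e-05 and 0.00213), and aromatic compound breakdown without 0.5x MBC (0.00552). With arrays or cultures left out, the adjusted p ran from 3.05e-22 to 4.15e-05 for the respiratory chain, 7.92e-12 to 0.00213 for TCA, 5.85e-09 to 0.925 for fatty acid and phenylacetate breakdown and 2.44e-08 to 0.314 for aromatic compound breakdown. With the slide row, the respiratory chain, TCA, and fatty acid and phenylacetate breakdown lists turned (0.469, 0.701 and 0.0467).

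Replicate numbers did not pair arrays: same-numbered deviations correlated at -0.008 to 0.27 across genes. The replicate block gave 2115, 1987, 647, 491 and 1384 genes for the 5 comparisons, and 88 genes (77 higher, 11 lower) for treated against untreated cultures on all arrays, a fit that takes the arrays of a culture as independent. The culture as a random block was not run for the dose comparisons, since each culture is its own group, and treated against untreated cultures was not run without the untreated one.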

Other observations

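The genes and groups in this part were picked after their values were seen, and no explanation was tested for them. Values are on the main scale, where the all-gene median against untreated was -0.88, -0.78 and -0.33 at the low, middle and high dose. With median centring it was 0.23, 0.26 and 0.05, so falls near 2-fold rest on the scaling. Among single genes with opposite calls, 4 that act on short-chain hydroxy and keto acids were on that main scale lower at 0.1x MBC and higher at 0.5x MBC. The beta subunit of acetoacetyl-CoA transferase, which activates acetoacetate, stood at -1.28 ± 0.12, 2.15 ± 0.12 and 1.58 ± 0.12 at the low, middle and high dose (ABAYE1914), and acetoacetyl-CoA thiolase at -1.53 ± 0.13, 1.76 ± 0.13 and 1.90 ± 0.13 (ABAYE1916). The dehydrogenase of hydroxybutyrate (ABAYE1909) stood at -1.57, 0.80 and 1.27, without a call at 0.25x MBC, and hydroxybutyryl-CoA dehydrogenase (ABAYE2368) at -2.68, 0.39 and 1.06, likewise without a call at 0.25x MBC.

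Of the genes with opposite calls, 2 annotated to lactate were higher at 0.1x MBC and lower at the other doses. The L-lactate permease (ABAYE3799), which imports lactate, stood at 1.36 ± 0.08, -3.27 ± 0.08 and -1.08 ± 0.08, and the lactate-responsive repressor LldR (ABAYE3798) at 1.68 ± 0.11, -1.90 ± 0.11 and -1.07 ± 0.11. All 6 values passed the threshold on the main scale, though those at 0.5x MBC lay close to the 2-fold minimum. Histidine ammonia-lyase (ABAYE0076) also turned, from 3.82 ± 0.12 at 0.1x MBC to -1.21 ± 0.12 at 0.25x MBC, and was not called at 0.5x MBC (-0.22 ± 0.12). An AHL-lactonase, which degrades quorum-sensing signals (ABAYE0618), stood at -1.07 and -1.14 at 0.1x and 0.25x MBC, near the all-gene medians of -0.88 and -0.78. The signal synthase (ABAYE3761) stood lower there, at -3.41 and -3.98. The hypothetical protein ABAYE1703 went from -3.42 ± 0.11 at 0.1x MBC to 3.69 ± 0.11 at 0.5x MBC.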
